A study of Mus musculus with 18 samples.

How the data were processed

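RNA from the livers of 18 mice was sequenced in 3 groups of 6 (wild-type C57BL/6J, Dp16 and Dp16-2xIFNRs), with 3 males and 3 females per group. Libraries were polyadenylated-RNA, strand-specific and paired-end. The deposited table of counts holds whole numbers for 55385 genes in each of the 18 libraries, and the deposited table of RPKM holds the same counts scaled by the authors to gene length and to the column total, which was checked on the file. The submitters' processing notes name bcl2fastq, FastQC 0.11.5, HISAT2 2.1.0, SAMtools 1.5 and HTSeq 0.6.1 with the genome build GRCm38. The version of bcl2fastq, the strand setting of the counting and the treatment of reads shared between genes are not given in the sources used here. Gene coordinates came from GENCODE M21, in which 99.56% of the gene identifiers were found, while the name of the deposited table points to a later release of the same build.

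Total counts per library ran from 38236222 to 59923315. Genes were kept with the filterByExpr rule of edgeR by group, which left 15208 genes; 106 gene symbols are used by more than 1 gene, and those genes were tested separately by identifier. Counts were scaled with TMM factors and tested with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3), with group and sex as terms, all 18 libraries in 1 fit and robust estimation. The median biological coefficient of variation was 0.339. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were called. Log2 CPM values used a prior count of 2. For the segment of chromosome 16 and the receptors, p values were also adjusted over the list alone.

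The groups, the tests, 34 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Lists were written from general knowledge of the tissue; 2 symbols were matched by an older name and 1 had no match. Markers of adipocytes and of pancreas had 4 and 2 tested genes, below the minimum of 5, and have no test. The receptors apart, the other 31 lists were tested with camera (limma 3.58.1) on voom values with a preset correlation between genes of 0.01, adjusted over the 31 lists; camera with an estimated correlation and fry were the alternatives. The count of libraries in a direction compares each library with the mean of the reference group, which holds both sexes; it is left out for the male-biased, female-biased and xenobiotic lists, where sex sets it. The interferon alpha score of a library is the mean log2 CPM over the list less the wild-type mean, compared with a two-sided exact permutation test over 924 arrangements, or 400 within sex. The difference between sexes was tested with an interaction term in edgeR and camera and by exact permutation within sex and group. The rule for named genes takes the receptors; outside the segment, the 10 called genes with the largest change in each direction, with a mean log2 CPM of at least 1 and no predicted or clone name; the 4 segment genes with the largest and the 4 with the smallest change above that level; and from each other list up to 4 called genes, or, where none passes, the 2 with the smallest p, as values only.

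Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors in edgeR, TMM without the segment, no low count filter, a CPM of at least 1 in 6 libraries, no sex term, age as a term, the replicate number as a block, the first digits of the number in the sample description as a term, that number, which some libraries of different groups share, as a random block, only the groups compared, each sex alone, limma on log2 RPKM with 0.1 or 1 added, and each library left out in turn. Added after the data were seen were 1 surrogate variable (sva 3.50.0), voom with sample quality weights, a gene length offset, and the fit without Dp16 libraries 4 and 5. Groups were also regrouped at random, with 100 splits per result. Planted changes of 1.5-fold, 2-fold and 4-fold served to test the edgeR fit on simulated data: against wild-type, it called 2 of 67, 25 of 67 and 47 of 66 changed Dp16 genes, and 5 of its 79 calls were unchanged genes. A fold against a group with 0 counts is a lower bound from a floor of 3 counts over the group. Of the values of single libraries that stood apart from their group, 2 are not reported here, and the counts of such values include them.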

Results

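Polyadenylated RNA from the livers of 18 adult mice was sequenced, with 6 wild-type C57BL/6J mice, 6 Dp16 mice and 6 Dp16-2xIFNRs mice, and 3 males and 3 females in each group. Dp16 mice carry an extra copy of the segment of mouse chromosome 16 that runs from Lipi to Zbtb21 (positions 75540514 to 97962622 of GRCm38), and they serve as a model of trisomy 21. The segment holds the interferon receptor genes Ifnar2, Il10rb, Ifnar1 and Ifngr2, which lie next to each other between positions 91372783 and 91565623. In Dp16-2xIFNRs mice the dosage of this receptor cluster is set back to that of wild-type, while the rest of the segment keeps its extra copy. The mice were 17.1 to 18.0 weeks old. Total counts per library ran from 38236222 in Dp16-2xIFNRs library 4 to 59923315 in Dp16 library 5, with group means of 48200000 ± 3650000 in wild-type, 48060000 ± 6950000 in Dp16 and 45440000 ± 4290000 in Dp16-2xIFNRs (SD, n = 6). The Y-linked gene Ddx3y exceeded Xist in 9 of 9 male libraries, and Xist exceeded Ddx3y in 9 of 9 female libraries. Dp16 libraries 4 and 5 stood apart from the rest, with the lowest and the highest TMM scaling factor (0.8026 and 1.338).

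The receptor genes followed the genotypes named in the labels. Ifnar1, a subunit of the type I interferon receptor, measured 22.3 ± 2.32 CPM (counts scaled to the library total and its TMM factor) in wild-type, 33.6 ± 7.05 in Dp16 and 23.1 ± 3.15 in Dp16-2xIFNRs livers (SD, n = 6). Ifnar2, its partner subunit, measured 61.6 ± 5.06, 88.1 ± 12.7 and 68.2 ± 6.95 CPM in the same order. Il10rb, a subunit shared by the receptors for interleukin 10 and type III interferon, measured 6.36 ± 1.58, 10.52 ± 2.85 and 7.09 ± 1.89 CPM. Ifngr2, a subunit of the type II interferon receptor, measured 29.5 ± 8.16, 37.6 ± 10.2 and 28.1 ± 6.98 CPM.

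**Figure D1:**
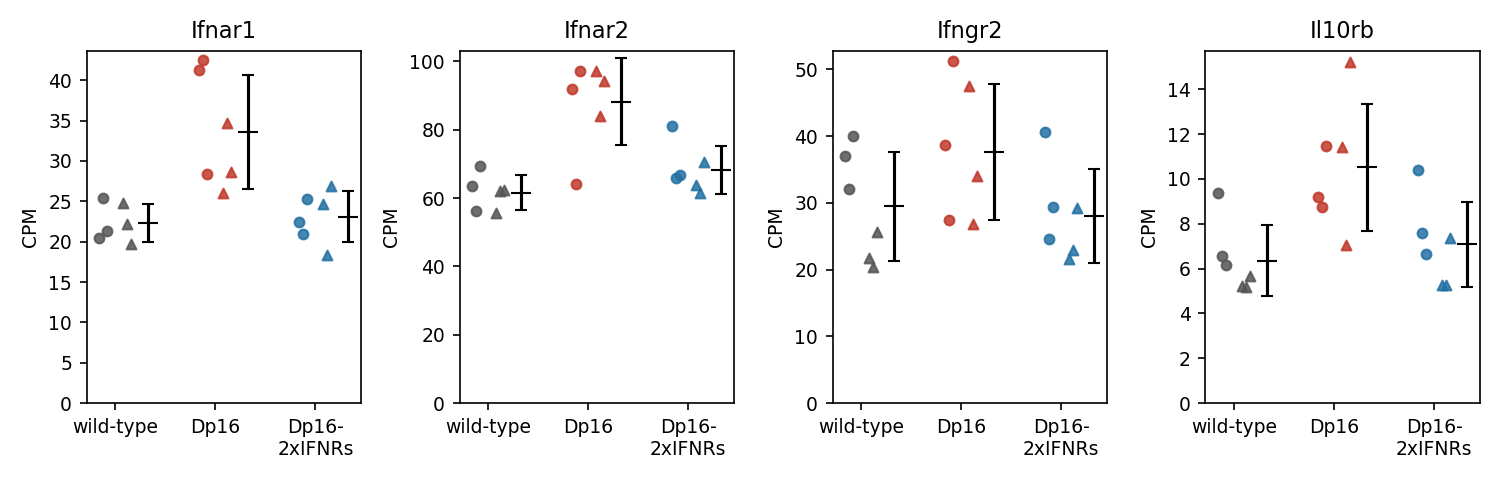
CPM of the 4 interferon receptor genes in each library, with circles for females, triangles for males and bars for the mean and SD of the 6 libraries per group. Mean Ifnar1 was 33.6 CPM in Dp16, 22.3 in wild-type and 23.1 in Dp16-2xIFNRs livers.

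The comparison of Dp16 with wild-type livers asks which transcripts accompany the extra segment when the interferon receptors are also present in 3 copies. Genes of the segment rose together: all 77 measured genes of the list fixed for it, which leaves out the 4 receptors, had a positive log2 fold change, with a median of 0.62 (1.53-fold, interquartile range 0.47 to 0.74, n = 6 mice per group). Genes of cholesterol synthesis fell together, with a median log2 fold change of -0.32 and all 25 of 25 members below wild-type. Genes of pericentral hepatocytes, the cells around the central vein of the liver lobule, also fell, with a median of -0.30 and 14 of 14 members below wild-type. Genes of stellate cells and the extracellular matrix rose, with a median of 0.31 and 19 of 21 members above wild-type.

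Outside these groups, few single genes passed the test, and the largest of them lie on other chromosomes. Esm1 (ENSMUSG00000042379.8, chromosome 13, positions 113209659 to 113218098), which encodes a proteoglycan secreted by endothelial cells, rose 6.37-fold (log2 2.67, SE 0.444, adjusted p = 0.0281, edgeR) from 0.762 ± 0.501 to 4.84 ± 2.09 CPM (SD, n = 6). Galnt15 (ENSMUSG00000021903.11, chromosome 14, positions 32028989 to 32062197), of the family of enzymes that start O-linked glycosylation, rose 2.75-fold (log2 1.46, SE 0.228, adjusted p = 0.0188) from 1.74 ± 0.388 to 4.78 ± 1.47 CPM. C4a (ENSMUSG00000015451.16, chromosome 17, positions 34809092 to 34823464), a paralog of the complement gene C4b that the table types as a long non-coding RNA, fell to 0.336 of its wild-type level (log2 -1.57, SE 0.244, adjusted p = 0.0188), from 13.9 ± 4.83 to 4.50 ± 1.27 CPM. Cyp2c50 (ENSMUSG00000054827.12, chromosome 19, positions 40089688 to 40113950), a cytochrome P450, fell to 0.45 of its wild-type level (log2 -1.15, SE 0.195, adjusted p = 0.0281), from 706 ± 146 to 318 ± 80.1 CPM. Tmem19 (ENSMUSG00000069520.6, chromosome 10, positions 115339674 to 115362501), which encodes a membrane protein, fell to 0.572 of its wild-type level (log2 -0.81, SE 0.137, adjusted p = 0.0281), from 115 ± 51.9 to 63.7 ± 25.1 CPM. Each of the other 4 genes lay on its side of the wild-type mean in 6 of 6 Dp16 libraries. Tmem19 differed by sex, with 67 to 101 CPM in Dp16 males beside 144 to 176 in wild-type males, and 37.1 to 49 CPM in Dp16 females beside 62.2 to 73.1 in wild-type females. The counts of C4a and Cyp2c50 depend on how reads shared with close paralogs were assigned, which is not given in the sources used here.

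The remaining call was the gene named a (ENSMUSG00000027596.10, chromosome 2, positions 154791402 to 155051012), which encodes the agouti signaling protein that sets hair color and is known from skin. It fell outside the rule for named genes and was chosen after its values were seen. It had 0 counts over the 6 wild-type libraries, 624 counts over the 6 Dp16 libraries (34 to 153 per library) and 496 over the 6 Dp16-2xIFNRs libraries (13 to 166 per library). Against a floor of 3 counts over the wild-type group, it was at least 196-fold higher in Dp16 (adjusted p = 0.000581, edgeR) and at least 184-fold higher in Dp16-2xIFNRs (adjusted p = 0.000613), in 6 of 6 libraries of each group.

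**Figure D2:**
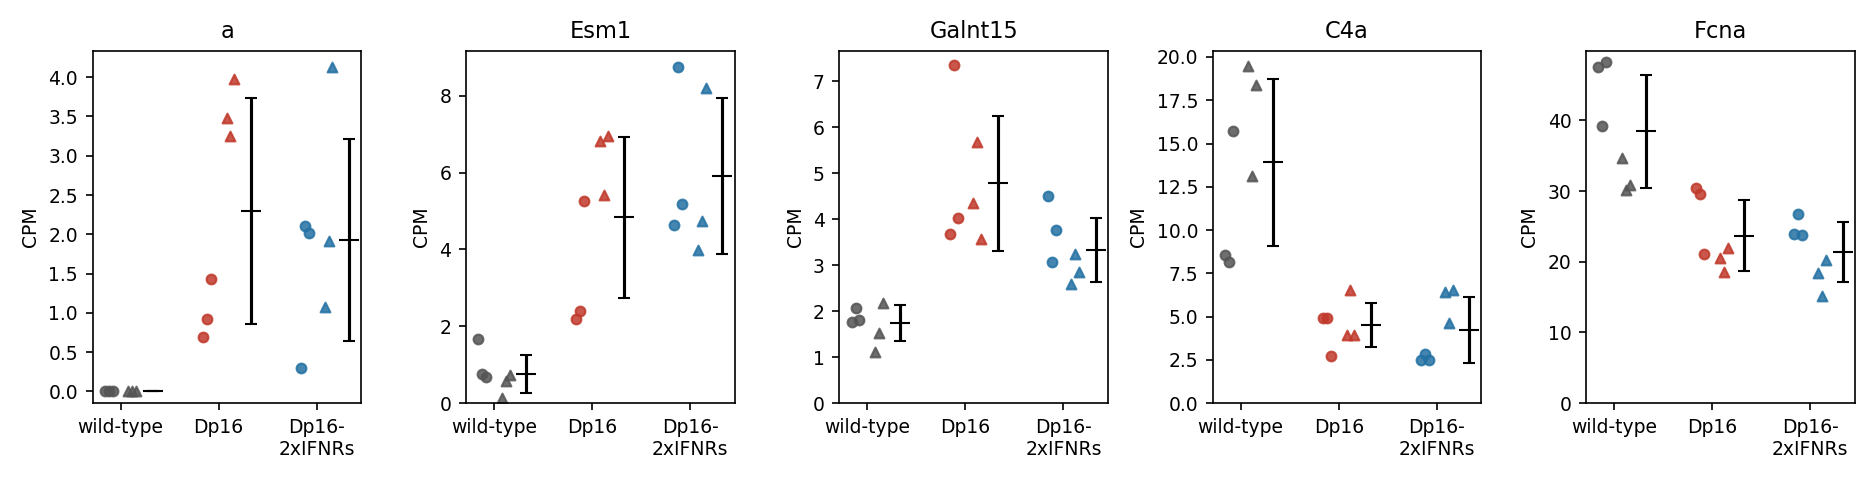
CPM of the genes a, Esm1, Galnt15, C4a and Fcna in each library, with circles for females, triangles for males and bars for the mean and SD of the 6 libraries per group. Gene a had 0 counts in every wild-type library and at least 13 counts in every library of the other groups.

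Over 15208 tested genes, 6 passed an adjusted p of 0.05 in Dp16, 3 higher and 3 lower, and 740 passed an unadjusted p of 0.05 (4.87% of the genes tested, 383 higher and 357 lower), a number that was 1409 without Dp16 4. DESeq2 called 72 genes and limma-voom 12, and the fit without Dp16 libraries 4 and 5, an alternative added after the data were seen, called 1. Leaving out single libraries took the count to 1 (without Dp16 2, wild-type 1 or wild-type 6), 2 (without Dp16 6, wild-type 2, wild-type 4 or wild-type 5), 3 (without Dp16 5 or Dp16-2xIFNRs 2) and, at the other end, 9 (without Dp16 4). Gene a kept its call in 18 of these 18 omissions, C4a in 13, Galnt15 in 12, Esm1 in 10, Cyp2c50 in 8 and Tmem19 in 7, with adjusted p values of up to 0.119 for Esm1, Cyp2c50 and Tmem19 and 0.0859 for Galnt15 without wild-type 2, and 0.0837 for C4a without Dp16 6.

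Within the segment, the genes with the largest changes among the better expressed members were Adamts5, an enzyme that cleaves matrix proteoglycans (log2 1.01, SE 0.224), Cbr1, a carbonyl reductase (0.89, SE 0.3), Dop1b (0.88, SE 0.329) and Hspa13, a heat shock protein relative (0.85, SE 0.326). Without Dp16 4 the values of Cbr1 and Hspa13 were 0.526 and 0.507. The smallest were those of Bace2 (0.21, SE 0.164), Ripply3 (0.19, SE 0.284), Jam2 (0.012, SE 0.178) and Erg (0.0099, SE 0.185). None of the 77 genes passed adjusted over all genes tested, and 29 passed adjusted over the list alone, all of them higher. An extra copy beside 2 copies corresponds to a log2 ratio of 0.585, and the 64 members with a mean log2 CPM of at least 1 had a median of 0.586. As a set the list rose with a camera adjusted p of 1.92e-35 (1.37e-08 with an estimated correlation) and in 6 of 6 Dp16 libraries. Adjusted over the list alone, the receptors Ifnar1 (log2 0.58, SE 0.147, adjusted p = 0.00168), Ifnar2 (0.52, SE 0.128, adjusted p = 0.00168) and Il10rb (0.75, SE 0.212, adjusted p = 0.00286) rose in 6 of 6 libraries, while Ifngr2 stood at 0.39 (SE 0.187, adjusted p = 0.0516) and lay above the wild-type mean in 4 of 6. Adjusted over all genes tested, these edgeR p values were 0.28, 0.246, 0.397 and 0.999, and none passed.

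**Figure D3:**
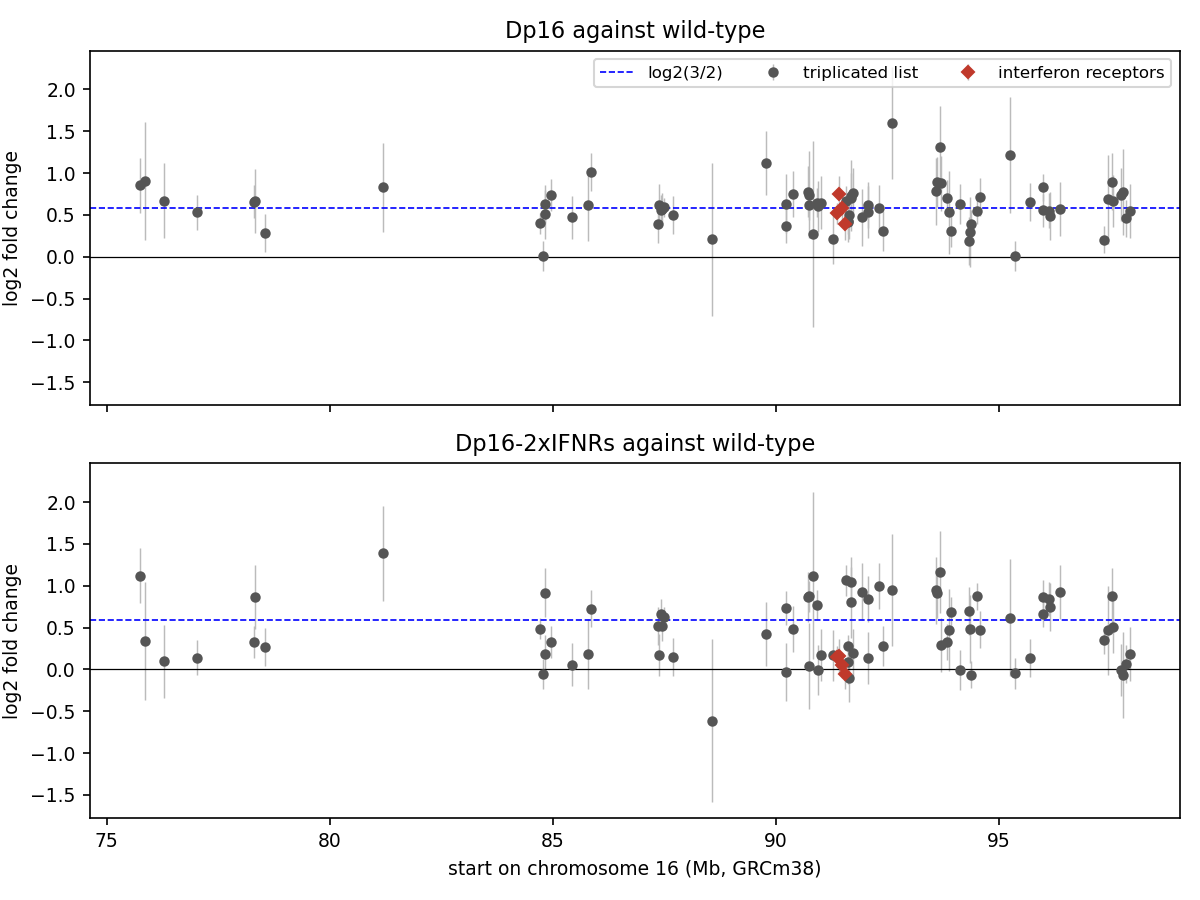
Log2 fold change with its SE against the start position on chromosome 16 (Mb) for the measured genes of the extra segment (grey circles) and the 4 interferon receptors (red diamonds), in Dp16 and in Dp16-2xIFNRs against wild-type. The dashed line marks a log2 ratio of 0.585, and the receptors lie near it in Dp16 and near 0 in Dp16-2xIFNRs.

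The fall of the cholesterol synthesis list was seen in 6 of 6 Dp16 libraries (camera adjusted p = 8.59e-13, 0.0193 with an estimated correlation). No member passed over all genes tested and 5 passed adjusted over the list alone; Msmo1, a sterol oxidase, stood at -0.89 (SE 0.199) and Mvd, of the mevalonate pathway, at -1.07 (SE 0.277). The fall of the pericentral list was seen in 5 of 6 libraries (adjusted p = 1.58e-06, 0.00759 with an estimated correlation). Its members Gulo, which makes ascorbate, and Cyp2e1, an ethanol-oxidizing cytochrome P450, stood at -0.49 (SE 0.116) and -0.55 (SE 0.151). The rise of the stellate and matrix list was seen in 6 of 6 libraries (adjusted p = 1.58e-06, 0.0308 with an estimated correlation), with Col1a2, a collagen I chain, at 0.71 (SE 0.219) and Loxl1, a collagen cross-linking oxidase, at 0.79 (SE 0.271). These 3 lists and the segment were the 4 of 16 called lists that also passed with an estimated correlation, and all 4 kept their call without each library in turn. The count of 16 fell to 10 without Dp16 6 or wild-type 1.

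The other 12 called lists were lost with an estimated correlation. Monocyte and neutrophil markers rose in 6 of 6 libraries, with a median log2 fold change of 0.73 (adjusted p = 6.29e-05, adjusted p = 0.0653 with an estimated correlation), and S100a8 and S100a9, calcium-binding proteins of neutrophils, stood at 1.65 (SE 0.467) and 1.40 (SE 0.401). Clock genes fell in 4 of 6 libraries, with a median of -0.49 (adjusted p = 0.00337, adjusted p = 0.102 with an estimated correlation), and Per2, a repressor of the clock, stood at -1.51 (SE 0.39). Xenobiotic metabolism fell, with a median of -0.21 (adjusted p = 0.000242, adjusted p = 0.263 with an estimated correlation), and Cyp2c50 was its called member. Bile acid genes fell in 4 of 6 libraries, with a median of -0.17 (adjusted p = 0.00541, adjusted p = 0.0927 with an estimated correlation), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at -1.22 (SE 0.436). These 4 lists kept their call without each library in turn.

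The other 8 called lists lost their call without some library. Targets of p53 rose in 5 of 6 libraries, with a median of 0.19 (adjusted p = 0.0145, adjusted p = 0.0653 with an estimated correlation, and 0.13 without Dp16 4), and Cdkn1a, a cell cycle inhibitor, stood at 2.03 (SE 0.507). Gluconeogenesis genes rose in 5 of 6 libraries, with a median of 0.14 (adjusted p = 0.0288, adjusted p = 0.263 with an estimated correlation, and 0.155 without wild-type 1), which was -0.125 in males and 0.376 in females, with Igfbp1 at 1.23 (SE 0.345). Erythroid markers rose in 5 of 6 libraries, with a median of 1.23 (adjusted p = 0.0292, adjusted p = 0.363 with an estimated correlation, and 0.342 without Dp16 4), with the globin gene Hba-a1 at 1.72 (SE 0.488, and 1.13 without Dp16 4). T and NK cell markers rose in 4 of 6 libraries, with a median of 0.66 (adjusted p = 0.0403, adjusted p = 0.495 with an estimated correlation, and 0.342 without Dp16 4), which was 1.74 in males and -0.339 in females. NF-kB targets rose in 5 of 6 libraries, with a median of 0.15 (adjusted p = 0.0403, adjusted p = 0.263 with an estimated correlation, and 0.236 without wild-type 1). Kupffer cell markers fell in 4 of 6 libraries, with a median of -0.086 (adjusted p = 0.0403, adjusted p = 0.584 with an estimated correlation, and 0.586 without wild-type 3), which was 0.316 in males and -0.587 in females, with Fcna, a complement-activating ficolin, at -0.69 (SE 0.126, adjusted p over all genes 0.0589). Male-biased genes fell, with a median of -0.069 (adjusted p = 0.0406, adjusted p = 0.271 with an estimated correlation, and 0.211 without wild-type 1).

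The interferon alpha list was not higher in Dp16 livers, in which receptor transcripts were. It fell in 4 of 6 libraries, all 3 males among them, and its scores were lower in males than in females in each group. The list had a median log2 fold change of -0.13, with 26 of 40 members below wild-type (camera adjusted p = 0.0162, adjusted p = 0.263 with an estimated correlation). The call was lost without wild-type 1 (0.0524), wild-type 4 (0.109) or Dp16 6 (0.137). Its member Ifi27 stood at -0.88 (SE 0.225) and Rtp4 at -0.43 (SE 0.165). The mean score of the list per library was lower by 0.119 log2 units than in wild-type on average (difference -0.119, group SD 0.228 and 0.221, n = 6), less than the spread between libraries (two-sided exact permutation p = 0.368 over 924 arrangements, 0.16 when permuted within sex). The interferon gamma and antigen presentation list had a median of -0.028, while its mean (0.107) and its test pointed upward (camera adjusted p = 0.646), and was not called. Its members Cxcl9, a chemokine induced by interferon gamma, and Irf8, a transcription factor, stood higher, at 1.07 (SE 0.371, and 0.707 without Dp16 2) and 0.51 (SE 0.228), each in 6 of 6 libraries. Tested in each sex alone, the list was called higher in males and lower in females, but the difference between the sexes did not pass with an estimated correlation (adjusted p = 0.309), and Kupffer cell and T and NK cell markers moved in the same directions.

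**Figure D4:**
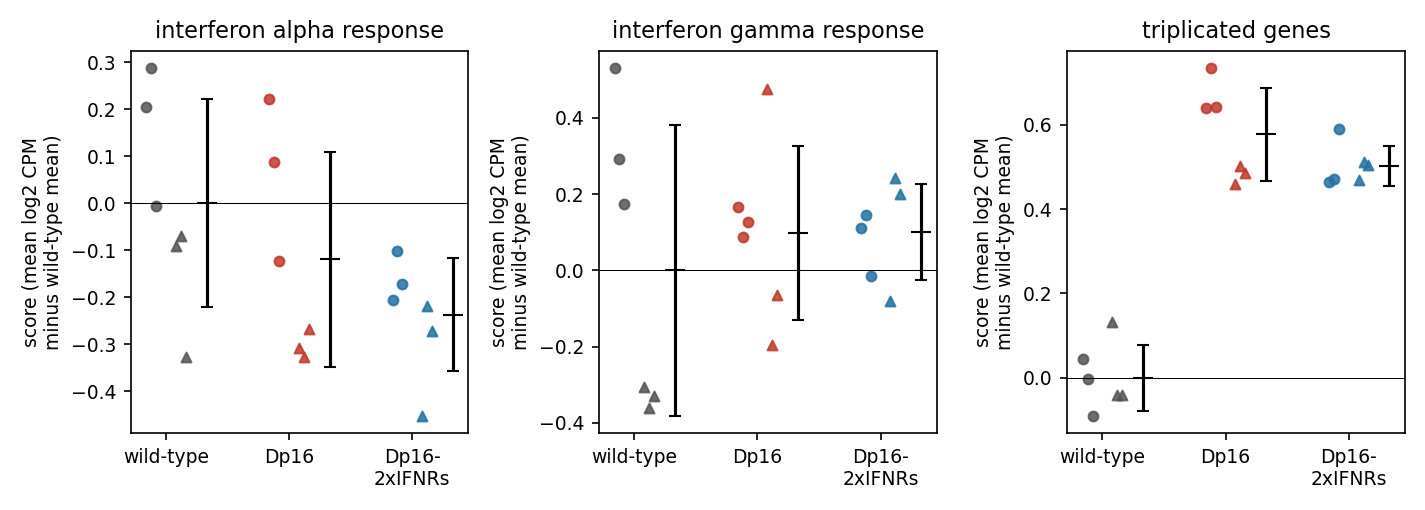
Mean log2 CPM over the interferon alpha, interferon gamma and chromosome 16 segment lists in each library, less the wild-type mean, with circles for females, triangles for males and bars for the mean and SD of the 6 libraries per group. The interferon alpha score averaged -0.119 in Dp16 and -0.236 in Dp16-2xIFNRs livers.

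The comparison of Dp16-2xIFNRs with wild-type livers asks what remains of the effect of the segment once the receptor dosage is normal. Genes of the segment rose again, with a median log2 fold change of 0.47 (1.39-fold, interquartile range 0.17 to 0.84, n = 6 mice per group) and 67 of 77 members above wild-type. Pericentral genes fell, with a median of -0.39 and 12 of 14 members below wild-type. Esm1 rose, and C4a and the ficolin Fcna fell. The 3 immunoglobulin G genes Ighg2c, Ighg2b and Ighg3 also rose, but none of them passed without Dp16-2xIFNRs 4. Interferon alpha response genes fell, with a median of -0.20 and 30 of 40 members below wild-type. This call was lost with an estimated correlation (camera adjusted p = 0.11) and kept by fry (adjusted p = 0.0193).

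Ighg2c (ENSMUSG00000076612.8, chromosome 12, positions 113285325 to 113288932) rose 11.6-fold (log2 3.53, SE 0.658, adjusted p = 0.037, edgeR) from 1.67 ± 1.97 to 17.5 ± 21.7 CPM (SD, n = 6), and Ighg2b (ENSMUSG00000076613.4, chromosome 12, positions 113302965 to 113307933) 8.24-fold (log2 3.04, SE 0.555, adjusted p = 0.0354) from 2.31 ± 2.13 to 16.6 ± 16.5 CPM. Both encode constant regions of immunoglobulin G. Dp16-2xIFNRs 4 held 60.6 CPM of Ighg2c and 48.8 of Ighg2b, beside 2.71 to 15.6 and 3.43 to 15.9 in the other libraries of its group. Without it the log2 fold changes were 2.85 and 2.58 and neither gene passed (adjusted p = 0.193 each). Esm1 rose 7.76-fold (log2 2.96, SE 0.439, adjusted p = 0.00803) to 5.91 ± 2.03 CPM (SD, n = 6). Acmsd (ENSMUSG00000026348.7, chromosome 1, positions 127729413 to 127767978), an enzyme of tryptophan breakdown, rose 2.93-fold (log2 1.55, SE 0.254, adjusted p = 0.021). C4a fell to 0.293 of its wild-type level (log2 -1.77, SE 0.246, adjusted p = 0.0056), at 4.23 ± 1.92 CPM. Fcna (ENSMUSG00000026938.10, chromosome 2, positions 25624666 to 25628030) fell to 0.557 (log2 -0.84, SE 0.127, adjusted p = 0.00803), from 38.5 ± 7.99 to 21.4 ± 4.26 CPM. Nsdhl (ENSMUSG00000031349.4, chromosome X, positions 72918557 to 72958514), a sterol-synthesis enzyme, fell to 0.656 (log2 -0.61, SE 0.114, adjusted p = 0.037). Each of these 7 genes lay on its side of the wild-type mean in 6 of 6 Dp16-2xIFNRs libraries. The immunoglobulin genes share close paralogs, so their counts depend on how shared reads were assigned.

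Of the 77 listed genes of the segment, 3 passed over all genes tested and 23 adjusted over the list alone, all of them higher. Tmem50b rose 2.09-fold (log2 1.07, SE 0.185, adjusted p = 0.0352). Cct8, a chaperonin subunit, rose 1.55-fold (log2 0.63, SE 0.115, adjusted p = 0.0354), and Vps26c, which takes part in the recycling of membrane proteins, rose 1.84-fold (log2 0.88, SE 0.162, adjusted p = 0.0357). Cct8 and Vps26c fell outside the rule for named genes, as did Ccl24, Ighg3, Gm5678, 1810064F22Rik and the gene a, and were chosen after their values were seen. Ccl24, a chemokine for eosinophils, fell to 0.24 of its wild-type level (log2 -2.06, SE 0.369, adjusted p = 0.0354). Ighg3 went from 5 to 643 counts over the group, and Gm5678, a predicted gene that lies inside the segment but not in its list, from 2 to 179 (adjusted p = 0.0354 each). The long non-coding RNA 1810064F22Rik rose with a log2 fold change of 2.55 (adjusted p = 0.0354). Among the better expressed genes of the segment, the largest values were those of Hspa13 (log2 1.12, SE 0.328), Tmem50b, Cryzl1 (1.05, SE 0.295) and Smim11 (0.99, SE 0.275), and the smallest those of Erg (-0.045, SE 0.186), Jam2 (-0.052, SE 0.177), Ttc3 (-0.065, SE 0.163) and Son, a splicing cofactor (-0.098, SE 0.288). With a gene length offset, an alternative added after the data were seen, Erg, Jam2, Ttc3 and Son stood at -0.0074, 0.16, 0.233 and 0.307. The 64 members with a mean log2 CPM of at least 1 had a median of 0.41. The median of the whole list was 0.547 with that offset and 0.566 with 1 surrogate variable, also added later. As a set, the segment rose with a camera adjusted p of 4.05e-20 (5.24e-07 with an estimated correlation), in 6 of 6 libraries.

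The receptors did not pass the test in Dp16-2xIFNRs livers: the log2 fold changes were 0.049 for Ifnar1 (SE 0.147), 0.15 for Ifnar2 (SE 0.127), 0.16 for Il10rb (SE 0.21) and -0.051 for Ifngr2 (SE 0.187), each with an edgeR adjusted p of 0.788 adjusted over the list alone. Over all 15208 tested genes, 15 passed, 11 higher and 4 lower, and 1317 passed an unadjusted p of 0.05 (8.66%, 521 higher and 796 lower), a number that was 2074 without wild-type 6. DESeq2 called 127 genes and limma-voom 19. With the description number as a random block 78 genes were called, 12 of the 15 among them. Leaving out single libraries took the count of 15 to 4 (wild-type 1, 2 or 5), 5 (Dp16-2xIFNRs 3 or wild-type 4), 6 (Dp16-2xIFNRs 4 or wild-type 6), 7 (Dp16-2xIFNRs 1 or 6, or wild-type 3) and 9 (Dp16-2xIFNRs 2), and to 24 without Dp16 5 and 48 without Dp16 4, libraries of the group outside this comparison that share its fit. C4a, Esm1, Fcna and the gene a kept their call in 18 of the 18 omissions, Acmsd in 12, Ighg2b, Ighg3 and Tmem50b in 9, Ccl24 in 8, Ighg2c and Gm5678 in 7, Cct8 and 1810064F22Rik in 5, Vps26c in 4 and Nsdhl in 3.

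Of 31 lists, 15 were called in Dp16-2xIFNRs against wild-type, 7 higher and 8 lower, and 2 passed with an estimated correlation: the segment, and the pericentral genes (adjusted p = 0.00014, 0.0418 with an estimated correlation, 6 of 6 libraries). Fry called 6 lists: the segment, the pericentral genes, and the cholesterol, interferon alpha, monocyte and neutrophil, and erythroid lists. Glul, the glutamine synthetase of pericentral hepatocytes, stood at -0.78 (SE 0.176). Monocyte and neutrophil markers rose with a median of 0.94 and 12 of 12 members above wild-type (adjusted p = 6.52e-05, adjusted p = 0.0847 with an estimated correlation), with S100a8 at 2.03 (SE 0.466). Erythroid markers rose with a median of 1.75 (adjusted p = 1.29e-06, adjusted p = 0.0847 with an estimated correlation), with Hba-a1 at 2.1 (SE 0.484). T and NK cell markers rose with a median of 0.62 (adjusted p = 0.00014, adjusted p = 0.21 with an estimated correlation), with Lck, a T cell kinase, at 1.33 (SE 0.473). The scores of these 3 lists lay above the wild-type mean in 6 of 6 libraries. For T and NK cell markers the median was 1.57 in males and 0.0837 in females. Wild-type 3, a female, scored 1.46 for them, above the highest Dp16-2xIFNRs library (0.944). B and plasma cell markers rose in 5 of 6 libraries with a median of 0.74 (adjusted p = 0.000578, adjusted p = 0.21 with an estimated correlation, and 0.0745 without wild-type 6), with the light chain gene Igkc at 2.86 (SE 0.593).

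Among metabolic lists, cholesterol synthesis fell in 6 of 6 libraries with a median of -0.33 (adjusted p = 5.95e-07, adjusted p = 0.089 with an estimated correlation), and Nsdhl was its called member. De novo lipogenesis fell in 5 of 6 libraries with a median of -0.51 (adjusted p = 0.000219, adjusted p = 0.355 with an estimated correlation), with Fasn, the fatty acid synthase, at -1.18 (SE 0.467). Clock genes fell in 5 of 6 libraries with a median of -0.71 (adjusted p = 0.00374, adjusted p = 0.148 with an estimated correlation), with Cry2, a clock repressor, at -0.78 (SE 0.235). ER stress genes rose in 5 of 6 libraries with a median of 0.26 (adjusted p = 0.00374, adjusted p = 0.21 with an estimated correlation), with the chaperones Creld2 at 1.25 (SE 0.512) and Manf at 1.12 (SE 0.448). These were 0.862 and 0.902 without Dp16-2xIFNRs 3, which held the most of both in its group, and 1.84 and 1.35 without wild-type 5. Fatty acid oxidation fell in 4 of 6 libraries with a median of -0.19 (adjusted p = 0.0179, adjusted p = 0.561 with an estimated correlation, and 0.286 without wild-type 2). Xenobiotic metabolism fell with a median of -0.16 (adjusted p = 0.0377, adjusted p = 0.514 with an estimated correlation, and 0.37 without wild-type 6), with the nuclear receptor Nr1i3 at -1.03 (SE 0.21). Bile acid genes fell in 5 of 6 with a median of -0.23 (adjusted p = 0.0398, adjusted p = 0.21 with an estimated correlation, and 0.239 without wild-type 6), with the bile acid uptake carrier Slc10a1 at -0.45 (SE 0.127). Periportal genes rose in 5 of 6 with a median of 0.17 (adjusted p = 0.0178, adjusted p = 0.126 with an estimated correlation, and 0.0646 without Dp16-2xIFNRs 2), with Gls2, a glutaminase, at 0.51 (SE 0.172).

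The interferon alpha list fell in 6 of 6 Dp16-2xIFNRs libraries (camera adjusted p = 0.00014, adjusted p = 0.11 with an estimated correlation), and its members Ifi27 and Ifih1, a sensor of viral RNA, stood at -0.88 (SE 0.225) and -0.62 (SE 0.159). The mean score differed from wild-type by -0.236 log2 units (group SD 0.12 and 0.221, n = 6, two-sided exact permutation p = 0.0476 over 924 arrangements, 0.02 when permuted within sex). With the median in place of the mean over genes the difference was -0.19 (exact permutation p = 0.0931). Without wild-type 4 the mean difference was -0.179 (exact permutation p = 0.0887) and without Dp16-2xIFNRs 1 it was -0.193 (exact permutation p = 0.106), and exact permutation p values above the threshold also came without wild-type 1 (0.0563), wild-type 2 (0.0584), wild-type 3 (0.0844), wild-type 6 (0.0758), Dp16-2xIFNRs 2 (0.0693), Dp16-2xIFNRs 3 (0.0758), Dp16-2xIFNRs 5 (0.0866) and Dp16-2xIFNRs 6 (0.0628). The interferon gamma list had a median of 0.036 (adjusted p = 0.812) and was not called.

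**Figure D5:**
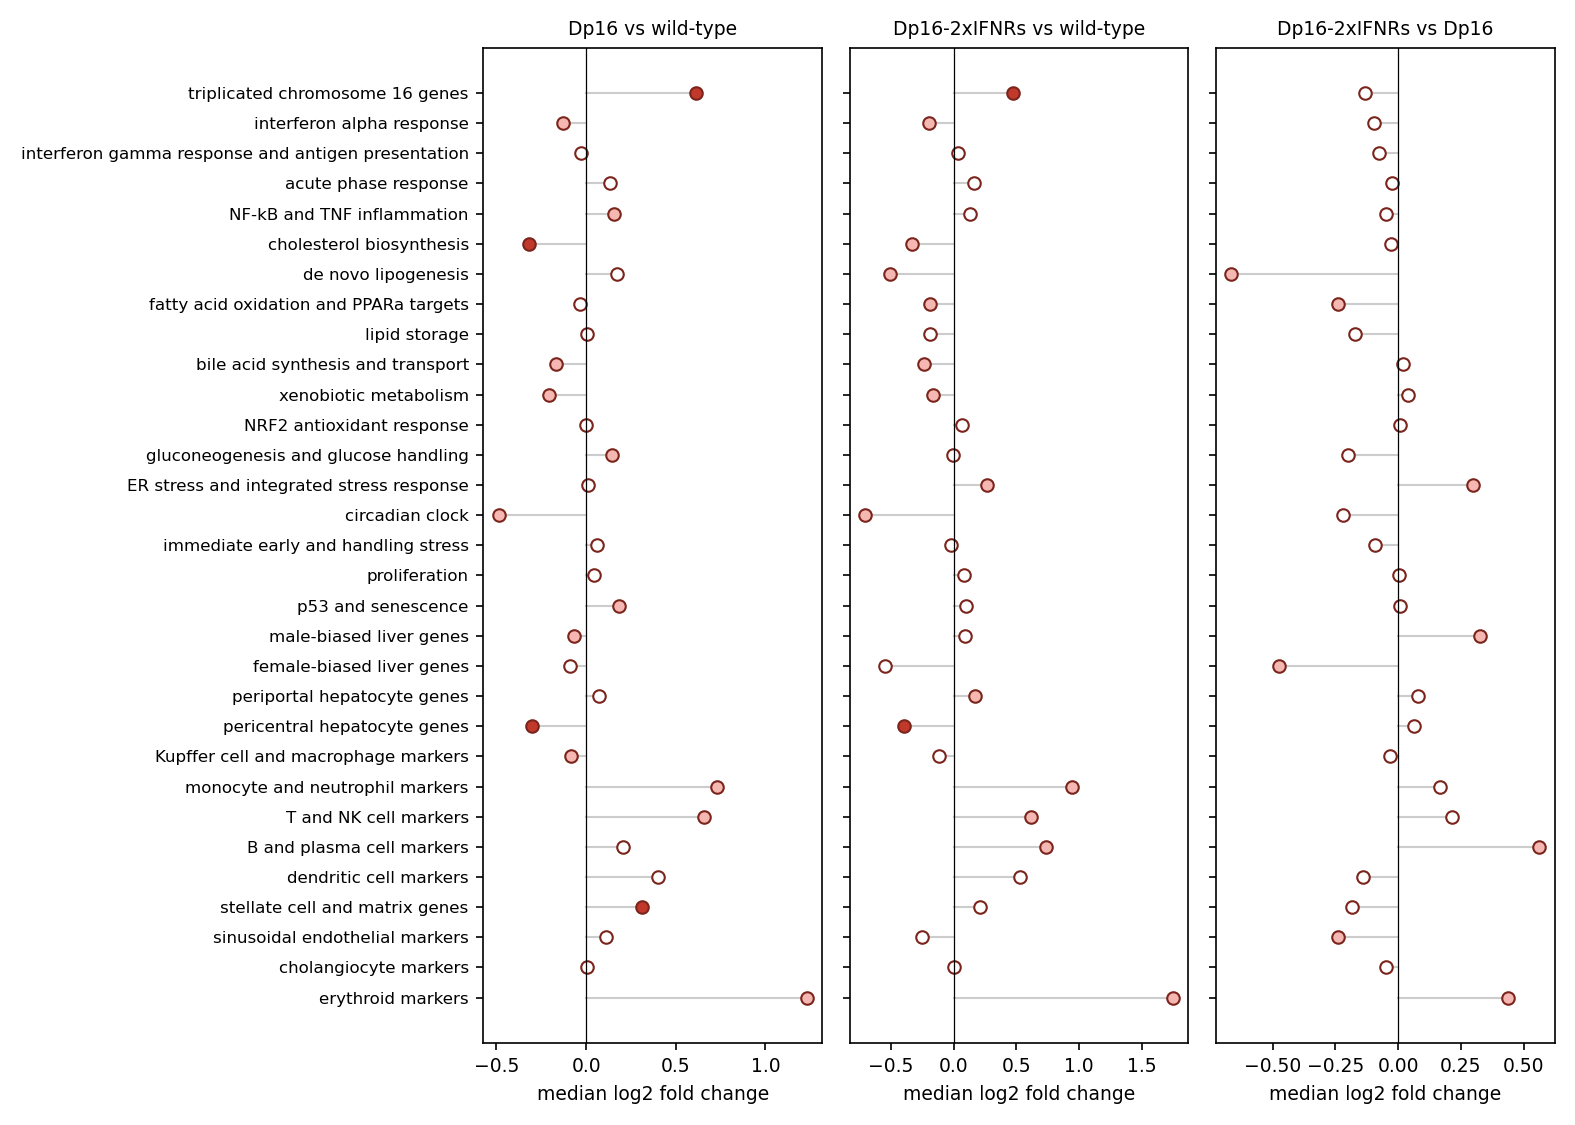
Median log2 fold change of each of the 31 lists in the 3 comparisons, dark where the list was called with the preset and with an estimated correlation, light where it was called with the preset correlation alone, and open where it was not called. The segment list stands at 0.62 in Dp16 and 0.47 in Dp16-2xIFNRs against wild-type.

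The comparison of Dp16-2xIFNRs with Dp16 livers asks what the return of receptor dosage to normal changes on the background of the segment. The receptors fell together: Ifnar1 by a log2 value of -0.53 (SE 0.147, adjusted p = 0.00723 adjusted over the list alone, 6 of 6 libraries), Ifnar2 by -0.37 (SE 0.127, adjusted p = 0.0147, 6 of 6), Il10rb by -0.59 (SE 0.211, adjusted p = 0.0147, 5 of 6) and Ifngr2 by -0.44 (SE 0.187, adjusted p = 0.0295, 5 of 6), with n = 6 mice per group and edgeR. Lipogenesis genes were lower in Dp16-2xIFNRs livers, with a median log2 fold change of -0.66 and 15 of 18 members below Dp16. This call was lost with an estimated correlation (camera adjusted p = 0.721) and by fry (adjusted p = 0.327). The medians against wild-type were -0.304 in Dp16-2xIFNRs and 0.697 in Dp16 females, beside -0.635 and -0.488 in males. Whether the gap differed between the sexes was not tested in this comparison. Dp16 5, a female, held the highest lipogenesis score of all libraries (1.15) and Dp16 4, a male, the lowest (-1.05). Erythroid markers were higher, with a median of 0.44 and 8 of 10 members above Dp16, and their call was lost in the same way (0.721 and 0.327). The rest of the segment did not pass as a set, with a median of -0.13, 30 members above and 47 below Dp16, and 0 genes adjusted over the list alone.

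No gene passed over all 15208 tested genes with edgeR, where the smallest adjusted p was 0.532, also that of each receptor. At an unadjusted p of 0.05, 1418 genes passed (9.32%, 336 higher and 1082 lower), and DESeq2 called 7 genes and limma-voom 0. With the description number as a random block 2 genes passed, and with sample quality weights, an alternative added after the data were seen, 3513 did. The 1418 became 4396 without Dp16 4, 554 without Dp16 5, 725 without Dp16 3 and 841 without Dp16 1. They became 751 with a gene length offset and 648 with 1 surrogate variable, both also added after the data were seen. The slope of log2 CPM, less the gene mean, on log2 gene length was -0.247 to -0.053 in Dp16-2xIFNRs libraries. In Dp16 it ran from -0.375 (Dp16 4) to 0.417 (Dp16 5), so a length trend may be part of this number and its direction. With known changes planted in simulated counts, of which 14706 genes were tested, the edgeR test called 3 of 67 genes changed 1.5-fold, 17 of 67 changed 2-fold and 51 of 66 changed 4-fold in this comparison, so changes of the size of the receptors' were rarely detectable over all genes.

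Of the 31 lists, 8 were called, 4 higher and 4 lower, none with an estimated correlation and none by fry. Random regroupings of these libraries called a median of 6 lists. Lipogenesis fell in 5 of 6 libraries (camera adjusted p = 0.000888, adjusted p = 0.721 with an estimated correlation), with Acacb and Acaca, acetyl-CoA carboxylases, at -1.35 (SE 0.436) and -1.24 (SE 0.416). With a gene length offset, also added after the data were seen, these became -0.717 and -0.608 while the list kept its call, and without Dp16 5 Acaca stood at -0.82. Erythroid markers rose in 6 of 6 libraries (adjusted p = 0.00771, adjusted p = 0.721 with an estimated correlation), with Alas2, the erythroid enzyme of heme synthesis, at 0.46 (SE 0.216, and 0.295 without Dp16 5). ER stress genes rose in 5 of 6 with a median of 0.30 (adjusted p = 0.0123, adjusted p = 0.721 with an estimated correlation, and 0.0933 without Dp16-2xIFNRs 3), with Sdf2l1 at 0.96 (SE 0.391). Male-biased genes rose with a median of 0.32 (adjusted p = 0.00935, adjusted p = 0.614 with an estimated correlation, and 0.0611 without Dp16 4), and female-biased genes fell with a median of -0.47 (adjusted p = 0.041, adjusted p = 0.721 with an estimated correlation, and 0.288 without Dp16 6), with Cyp3a16, of the cytochrome P450 family 3, at -2.97 (SE 0.6). B and plasma cell markers rose in 5 of 6 with a median of 0.56 (adjusted p = 0.0383, adjusted p = 0.721 with an estimated correlation, and 0.184 without Dp16-2xIFNRs 4), with Mzb1 at 1.94 (SE 0.839). Sinusoidal endothelial markers fell in 6 of 6 with a median of -0.24 (adjusted p = 0.041, adjusted p = 0.799 with an estimated correlation, and 0.126 without Dp16 3), with Stab2, a scavenger receptor, at -0.90 (SE 0.344). Fatty acid oxidation fell in 4 of 6 with a median of -0.24 (adjusted p = 0.048, adjusted p = 0.86 with an estimated correlation, and 0.499 without Dp16 1). The count of 8 fell to 4 without Dp16 4 or Dp16-2xIFNRs 5, and to 5 without Dp16 2, Dp16-2xIFNRs 1, Dp16-2xIFNRs 4, wild-type 1 or wild-type 3.

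Interferon response genes did not pass in the main fit of this comparison. The interferon alpha list had a median of -0.0975 with 27 of 40 members below Dp16 (camera adjusted p = 0.209), and the score differed by -0.117 log2 units (two-sided exact permutation p = 0.305, 0.155 when permuted within sex, n = 6). With a gene length offset, an alternative added after the data were seen, the list passed (median -0.0851, camera adjusted p = 0.0229). Samd9l, an interferon-induced gene, stood at -0.72 (SE 0.242), and at -0.439 with the offset. The interferon gamma list had a median of -0.075 (camera adjusted p = 0.914). Its member Nlrc5, an activator of MHC class I genes, stood at -1.22 (SE 0.539), and at -0.657 with the offset.

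Outside the 77 listed genes of the segment and the receptors, 3 of 15127 genes were called in the same direction in both comparisons with wild-type: Esm1 and the gene a higher, and C4a lower. Both comparisons use the same wild-type libraries. Independent calls would share 0.00159 higher and 0.000793 lower genes, and 20 simulations of unchanged groups against shared controls gave at most 0. Unchanged groups leave few calls to share, so this 0 cannot show whether shared controls raise the overlap. With the wild-type libraries split 3 and 3, so that each comparison had its own controls, 1 gene was shared in each of 20 splits. The log2 fold changes of both comparisons correlated across genes with r = 0.543, beside 0.475 to 0.534 in the simulations and a median of 0.152 (-0.162 to 0.275) with the controls split; genes are not independent replicates. Their covariance was 0.1695, beside a mean of 0.1349 in the simulations, while the share of genes with the same sign, 56.59%, lay below the simulated mean of 66.63%.

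No gene passed the edgeR test for a response that differed between the sexes, in Dp16 (1198 genes at an unadjusted p of 0.05, smallest adjusted p 0.378) or in Dp16-2xIFNRs (340 genes, smallest adjusted p 0.566). DESeq2 called 52 and 10 genes in these tests, and 1 gene passed in Dp16 when wild-type 1 was left out. The interferon gamma and antigen presentation list moved in opposite directions. In Dp16 its median log2 fold change was 0.12 in males and -0.22 in females (camera adjusted p of the difference 8.06e-06, 0.309 with an estimated correlation). In Dp16-2xIFNRs it was 0.24 in males and -0.31 in females (camera adjusted p of the difference 6.51e-14, 0.0455 with an estimated correlation). By exact permutation the p adjusted over the lists was 0.155 in both groups. Kupffer cell markers moved alike in Dp16-2xIFNRs, with medians of 0.205 in males and -0.387 in females. T and NK cell markers stood at 1.57 and 0.0837 there.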

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

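The tests of Krt1, Krt5 and Krt14, of Krt10 alone, of Raly and of age below were chosen after the results were seen. The interferon gamma list changed in opposite directions in the sexes. The score of this list responded more in males than in females by 0.609 in Dp16 and by 0.704 in Dp16-2xIFNRs (n = 3 per sex and group). The exact permutation p was 0.005 in both, the smallest that 400 arrangements can give, and 0.155 in both after adjustment over the 31 lists. Leaving out each library in turn left at least 0.669 of the difference (without Dp16 2), which argues against 1 library as its source. With a score of immune cell markers as a covariate, 0.723 of the difference was left in Dp16 and 0.831 in Dp16-2xIFNRs, so part of it may go with the content of immune cells, and the 3 mice per sex and group keep this open.

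Other lists also differed between the sexes by camera with the preset correlation. In Dp16 the differences of scores, males less females, were 0.5 for the acute phase response, -1.19 for de novo lipogenesis (median -0.49 in males and 0.70 in females), 0.675 for Kupffer cell markers and 1.2 for T and NK cell markers (median 1.74 in males and -0.339 in females). In Dp16-2xIFNRs they were 0.566 for the acute phase response, 0.8 for NF-kB targets, 0.561 for immediate early genes, 0.568 for Kupffer cell markers and 0.779 for T and NK cell markers. Wild-type 3, a female in both comparisons, held a T and NK cell score of 1.46, beside 0.00175 and 0.0757 in the other wild-type females. These differences were not retested without single libraries. Of the 5 and 6 lists that differed, 0 and 1 did so with an estimated correlation, and 3 and 2 of the 31 lists had an exact permutation p below the threshold before adjustment.

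Dp16 libraries 4 and 5, both from mice of 17.1 weeks, lay far apart on the first component of the 18 libraries, at -99.8 and 55.5. Group and sex had been taken out before this component was computed. The distance of both libraries was 0.983 of its whole range, which argues against age as the only cause. Wild-type 6, also of 17.1 weeks, lay at -65.6 and wild-type 5, of 17.6 weeks, at -36.8, so a part for age stays open. Thinning all libraries to equal depth left 1.03 of the share of this component, which argues against depth. Removing the trend with gene length left 0.727 of the share (25.8% before, 18.7% after), so a length trend may be part of it. The design holds no record of the handling of single mice, and no biological explanation was tested.

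Gene a was counted in 12 of the 12 libraries that carry the segment and in 0 of 6 wild-type libraries. Krt1, Krt5 and Krt14, keratins of skin, had 3 counts over these 12 libraries beside 1120 of gene a, which argues against RNA from skin. The summed CPM of Krt1, Krt5, Krt10 and Krt14 was above that of gene a in 7 of the 12 libraries, as RNA from a keratinized tissue would have it, and below it in 5. Krt10 made up nearly all of this sum, with a mean of 93.9 counts per carrier library and 48.2 per wild-type library, where gene a had none. Over the carriers Krt10 rose and fell with gene a (Spearman correlation 0.937, higher than for any other of 15207 tested genes), so a tissue or cell type that holds Krt10 without the other 3 keratins stays open as a source of both. Raly overlaps gene a on the same strand, and its mean in wild-type was 0.934 of that in the carriers (56.8 and 60.8 CPM), which argues against its reads as the source. A segment of another strain around gene a could not be told from none: 0 of 67 tested neighbors within 2 Mb passed an unadjusted p in both comparisons, where 1.4 would by chance. C57BL/6J mice are nonagouti, so an agouti allele in the mice that carry the segment is a candidate explanation that these counts cannot test. Gene a lies on chromosome 2, apart from the segment on chromosome 16.

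Of 591 groups of 6 values, 76 held a single library far from the other 5. Chance would give about 1 in 20 groups (29.6) if the values were normally distributed. The CPM of genes entered without a log transform, so the excess alone is not evidence of unusual libraries. Of the 76, 30 were in wild-type, 22 in Dp16 (9 of them in library 4 and 2 in library 5) and 24 in Dp16-2xIFNRs. Manf and Creld2, chaperones of the endoplasmic reticulum, were highest in 1 male library of each group: Manf at 238 CPM in wild-type 5, 442 in Dp16 4 and 492 in Dp16-2xIFNRs 3, and Creld2 at 168, 137 and 304 in the same libraries. Sdf2l1 (198), Hspa13 (156), Smim11 (34), Mvd (44.9), Fabp4 (35.7) and Cxcr6 (3.46) also stood apart in Dp16 4, with a gluconeogenesis score of -0.216. Immunoglobulin genes were highest in wild-type 3 (Igkc 49.9, Ighg2c 5.58, Ighg2b 6.34), Dp16 6 (Ighg2c 19.9, Ighg2b 21.9) and Dp16-2xIFNRs 4 (Igkc 271, Ighg2c 60.6, Ighg2b 48.8). Cdh1, the epithelial cadherin, was highest in wild-type 1 (79.8), Dp16 3 (90.6) and Dp16-2xIFNRs 1 (64.3). The descriptions of these 3 libraries carry the same number, as do those of wild-type 5 and Dp16-2xIFNRs 3 (but not Dp16 4) among the libraries high in Manf. What the number stands for is not given in the sources used here, and whether it bears on these values was not tested.

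The other single values reported, in CPM for genes, were these. In wild-type: library 1, a clock score of -0.81, Jam2 14, Cdkn1a 16.6, Selenbp2 1292 and Cyp1a2 1020; library 2, Plin4 1.29 and Pdgfra 1.7; library 3, a bile acid score of -0.326, a T and NK cell score of 1.46, Il10rb 9.4, Rtp4 19.1, Irf8 12.1, G6pdx 27.7, Atf3 4.35, Sox4 6.49, Acss2 933 and Ppargc1a 6.62; library 4, Serpina3n 514; library 5, Hspa13 64.7, Thrsp 2375 and Rrm2 12.3; library 6, Cyp3a41b 70.6 and Cd2 2.08. In Dp16: library 2, a protein-coding share of 96%, a long non-coding share of 2.9%, a cholangiocyte score of -1.19, Cxcl9 95.5 and Siglech 1.25; library 3, Fga 6957 and Aurkb 1.43; library 5, Acaa2 414 and Col1a2 29.5; library 6, Acta2 8.56. In Dp16-2xIFNRs: library 1, a T and NK cell score of 0.24 and Fga 5315; library 2, an NRF2 score of -0.0583, Rtp4 13.9, Xcr1 0.374, Il6ra 21.9, Ier3 1.29 and Col5a1 7.79; library 3, Mvd 57.8; library 5, an RPKM sum of 667197, Cxcl9 64.8, Loxl1 1.89 and Hspa1b 7.14; library 6, Mki67 1.88, Rrm2 8.85, Acaca 98.4 and Slc4a1 4.26.

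Random regroupings of the libraries asked whether chance can be excluded, with 100 splits for each result, the real one included. For the comparisons of 2 groups, these were drawn from 462 possible splits. In Dp16, only the real split of those drawn was as large for the segment (median 0.62, highest other 0.482, 1 split as large) and the receptors (0.55, highest other 0.473, 1 split as large). The 6 called genes were reached by 4 splits, under 0.05 of them, but 3 other splits called over 100 genes, up to 3933, which points to a structure of the samples. All 3 held wild-type 1 and Dp16 3 with Dp16 5, and wild-type 3, 5 and 6 with Dp16 4. On the first component, wild-type 1 (58.2) and Dp16 3 (56.9) lay beyond Dp16 5 (55.5), so the structure is not that of Dp16 4 and 5 alone. Chance cannot be excluded in Dp16 for interferon alpha (-0.13, highest other 0.244, 14 splits), interferon gamma (-0.028, 0.419, 87) or the 16 lists (highest other 17, 5 splits). In Dp16-2xIFNRs, only the real split was as large for the 15 called genes (highest other 0, 1 split) and the segment (0.47, 0.38, 1). Chance cannot be excluded in this group for the receptors (0.098, 0.291, 40), interferon alpha (-0.20, 0.294, 10), interferon gamma (0.036, 0.313, 71) or the 15 lists (21, 7 splits). Between Dp16-2xIFNRs and Dp16, only the real split of those drawn was as large for the receptors (-0.49, 0.474, 1), by a narrow margin. The segment (-0.13, 0.174) was reached by 4 splits, the real one included, which is under 0.05 of them. It did not pass as a set (camera adjusted p = 0.614). Its median was -0.0206 with a gene length offset, -0.0176 with 1 surrogate variable and -0.0592 over its 64 better expressed members. Many results were tested by splits without adjustment, so chance is not called excluded for the segment, nor for the results that only the real split reached. Chance cannot be excluded for interferon alpha (-0.0975, 0.247, 27), interferon gamma (-0.075, 0.563, 60) or the 8 lists (16, 37). In the other splits a median of 8 lists was called in Dp16, 8 in Dp16-2xIFNRs and 6 between both. List calls with the preset correlation were thus common among regrouped libraries. The 0 genes called between Dp16-2xIFNRs and Dp16 (highest other 0) and the 0 genes of the sex interaction leave nothing to test, since all 100 splits reach a count of 0. For the interaction in Dp16 the highest other count was 5718 (in a split with Dp16 4 and Dp16 5 on the same side, again a structure of the samples), and in Dp16-2xIFNRs it was 0. For the 3 shared calls 1 of 100 splits was as large (highest other 0); an earlier draw of fewer splits held one with many more, so this rests on the splits drawn.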

How the results depend on the processing

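The fits with 1 surrogate variable, sample quality weights, a gene length offset, or without Dp16 libraries 4 and 5 were tests chosen after the results were seen. Of 739 values of the main results under an alternative, 638 were kept, and of 8418 values of named genes, 7906 were. Counts were judged by their ratio to the main count. Other values were judged by their side of the threshold, and by sign where either fit called them. Of the gene values, 264 lost a call, 248 gained one and 0 changed sign with a call. The 264 all belong to the genes called in the main fit, 6 in Dp16 and 15 in Dp16-2xIFNRs. Most named genes were not called there, and a value that stayed uncalled counted as kept. The share kept therefore says little about how the calls fared. Sign changes of uncalled values were counted as kept. Son in Dp16-2xIFNRs was 1 of these, at -0.098 and, with the gene length offset, at 0.307. Genes called in Dp16 (6), Dp16-2xIFNRs (15) and Dp16-2xIFNRs against Dp16 (0, edgeR, 1418 at an unadjusted p of 0.05) became 72, 127 and 7 with DESeq2; 12 in Dp16 with limma-voom; 3 and 7 without a sex term; 16, 78 and 2 with the description number as a random block (correlation 0.41); 1 and 43 with only the groups compared; 0 and 0 in males only and 0 and 0 in females only, where fewer libraries enter; 12 and 45 with limma on log2 RPKM plus 0.1; 12 and 23 with 1 added; 102 and 77 with 1 surrogate variable; 18, 412 and 3513 with sample quality weights; 21 and 48 with a gene length offset; and 1 and 64 without Dp16 libraries 4 and 5. The description series gave 23 in Dp16-2xIFNRs. All 6 Dp16 calls were among those of DESeq2, 1 surrogate variable and the length offset. With the replicate block, 5, 21 and 0 genes were called. The numbers do not pair the libraries: 18 pairs with the same number correlated at -0.245 to 0.36, and 3 of 18 libraries were closest to one with their own number. The interferon alpha median in Dp16 lost its call with the description series (-0.108, adjusted p = 0.0589), in males (-0.109, 0.142) and in females (-0.0507, 0.0942); in Dp16-2xIFNRs it did in males (-0.142, 0.0906), and against Dp16 it passed with the length offset (-0.0851, 0.0229). The interferon gamma median was 0.133 in males (reversed, adjusted p = 5.77e-05) and -0.226 in females (0.00602) of Dp16, and 0.244 in males (0.000166) and -0.321 in females (reversed, 2.05e-05) of Dp16-2xIFNRs. The receptors against Dp16 no longer passed as a set (camera) in females, at a median of -0.288. Lists called (16, 15 and 8) were 4, 2 and 0 with an estimated correlation and 4, 6 and 0 with fry. The interferon alpha score of Dp16-2xIFNRs by the median was -0.19 (exact permutation p = 0.0931). Interaction genes (0 and 0) were 52 and 10 with DESeq2 and 1 and 1 with no low count filter. Shared calls (3) were 44 with DESeq2, 33 with 1 surrogate variable, 11 with quality weights, 10 with the length offset, 1 without Dp16 libraries 4 and 5 and 1 with the wild-type libraries split. Where no reason is given, the cause was not tested. Leaving out 1 library gave, for Dp16, Dp16-2xIFNRs and the comparison of both, called genes of 1 to 9, 4 to 48 and 0 to 0; lists of 10 to 17, 12 to 18 and 4 to 8; segment medians of 0.586 to 0.648, 0.421 to 0.509 and -0.161 to -0.08; receptor medians of 0.516 to 0.564, 0.0464 to 0.137 and -0.552 to -0.427; interferon alpha medians of -0.167 to -0.0624, -0.244 to -0.171 and -0.177 to -0.0564; interferon gamma medians of -0.068 to 0.0612, -0.0972 to 0.0839 and -0.109 to 0.0646; interferon alpha scores of -0.188 to -0.0618, -0.302 to -0.179 and -0.159 to -0.0487; and interaction genes of 0 to 1 and 0 to 0.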

Other observations

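Besides the interferon gamma list, the lists that were not called in any comparison covered the acute phase, lipid storage, NRF2 targets, immediate early genes, proliferation, dendritic cells and cholangiocytes. Their median log2 fold changes in Dp16 and in Dp16-2xIFNRs against wild-type were 0.13 and 0.17 for the acute phase response, 0.0050 and -0.19 for lipid storage, -0.0029 and 0.069 for NRF2 targets, 0.063 and -0.021 for immediate early genes, 0.047 and 0.081 for proliferation, 0.40 and 0.53 for dendritic cell markers and 0.0056 and 0.0062 for cholangiocyte markers. Among these lists, the median, mean and test differed in sign for NRF2 targets, proliferation and cholangiocytes in Dp16 and for lipid storage, immediate early genes and cholangiocytes in Dp16-2xIFNRs.

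The genes of this paragraph were chosen after their values were seen. Dp16 library 5 held 225 CPM of Neat1, a nuclear long non-coding RNA, beside 2.889 to 22.91 in the other Dp16 libraries, 3.475 to 18.89 in wild-type and 1.55 to 5.771 in Dp16-2xIFNRs. It also held 41.9 CPM of Malat1, likewise nuclear, which ranged from 3.611 to 21.45 in the other Dp16 libraries, from 13.62 to 34.29 in wild-type and from 3.472 to 22.84 in Dp16-2xIFNRs and so stood less far apart, and 175.6 CPM of Xist, beside 11.07 to 48.31 in the other 8 female libraries. C4b, the paralog of C4a, ranged from 436.1 to 987.8 CPM in wild-type, from 290.3 to 1096 in Dp16 and from 378.3 to 522.2 in Dp16-2xIFNRs libraries. Its log2 fold change against wild-type was 0.0721 (SE 0.2765) in Dp16 and -0.686 (SE 0.2773, edgeR adjusted p = 0.523) in Dp16-2xIFNRs, so it was also lower in the latter group, by less than C4a.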
